A study of Mus musculus with 1677 samples.

How the data were processed

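Polyadenylated RNA from 22 mouse tissues was sequenced as stranded libraries, each run 1 to 4 times. Per the submitters' processing notes, base calls came from CASAVA 1.8, read quality from FastQC 0.11.8, alignment to the mouse genome (GRCm38, mm10) from STAR 2.5.3a, and gene quantification from HOMER 4.10. The deposited table holds 1 column of expected counts per library and 24537 rows named by gene symbol. Of its values 29.62% are not whole, and values were rounded to the nearest integer, ties to the even one, before they were modelled as counts. All columns mapped to a labelled library through the library names given in the labels (0 columns were unmapped). The labels of the ileum and liver libraries give hours from 24 to 46 and were read as the same clock times of a day, ZT0 to ZT22. The names of 26 rows read as dates. The 4 of these rows named Mar-01 or Mar-02, whose names are duplicated, were left out, which leaves 24533 rows. No column was identical to another.

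Each tissue was fitted on its own with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr over the feeding groups, libraries were scaled by TMM, and quasi-likelihood negative binomial models were fitted with glmQLFit. The choices in this paragraph and the next were made before the data were examined. The mean-level comparison had clock time as a factor of 12 levels plus the feeding group. The window comparison replaced the feeding term by one for ZT0 to ZT12 and one for ZT14 to ZT22, and tested each and their difference. The rhythm comparison fitted a cosine and a sine of 24 h in each feeding group and tested both coefficients in ALF, in TRF and as a difference. Amplitudes, peak times and their standard errors came from limma 3.58.1 on log2 CPM. Benjamini-Hochberg adjustment was done within a tissue and test, with 0.05 as the threshold. Errors after ± are standard errors of the log2 fold change (TRF minus ALF), and n counts libraries.

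A total of 40 gene lists (pathways, and markers of cell types that a dissected tissue could carry) were fixed in advance and tested with limma camera on log2 CPM at a preset correlation of 0.01, where at least 5 members were tested. Benjamini-Hochberg adjustment ran over lists and tissues within a contrast, and each test was repeated with the correlation estimated per list. Counts adjusted over the list alone apply Benjamini-Hochberg to the list's members only. None of these 40 lists was chosen on these libraries. The adipose-enriched genes used further below were picked from these libraries. For genes changed in many tissues, counts were set beside random lists of the same sizes. Named genes followed a fixed rule: the 15 that rose and the 15 that fell in the most tissues, and in each tissue the 2 largest rises and 2 largest falls in log2 fold change at an adjusted p under 0.05, with a mean of at least 5 CPM and the same sign among replicate 1 and among replicate 2 libraries. In each window it took 1 each way, then up to 4 members with the smallest p of each list that passed, and all core clock genes. The text gives a selection of these. Genes tested by GC content used the transcripts of GENCODE vM21, and coordinates are GRCm38.

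The models were tested on simulated data made from the brown fat, dorsomedial hypothalamus and liver counts with 200 changed genes. At a log2 fold change of 0.5 the mean-level test found 76%, 59% and 95% of the changed genes, and at 1 it found 95%, 96% and 100%. It called 10 of 13109, 7 of 14310 and 13 of 12156 unchanged genes. The changed genes were drawn from those with a mean of at least 5 CPM. Counts were simulated independently for each gene, for this test without a daily course. They held no GC trend and no deviations shared by the genes of a library, so these rates may not hold in the real libraries. Simulated peaks at 8 h were read at medians of 8.00, 7.97 and 8.03 h. Total counts per library ran from 2.26 to 501 M, which sets the counting precision, and 3 libraries exceeded 100 M.

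Alternatives fixed in advance were DESeq2 size factors, no filter on low counts, the replicate number as a block, each replicate number left out, each clock time left out, DESeq2 1.42.0 in place of edgeR, the boundary times ZT0 and ZT22 left out of the windows, a second harmonic of 12 h, a minimum log2 amplitude of 0.25, and stricter thresholds for genes shared by tissues. The replicate numbers did not pair ALF with TRF libraries: over 245 comparisons of the residuals of libraries with the same number the correlation ran from -0.779 to 0.799, with 83 above 0.1 and 62 below -0.1, so the block stayed an alternative. Alternatives added after seeing the data were GC content offsets (a lowess trend with a span of 0.3 for each library), the number of runs or the presence of fractional counts as a term, removal of libraries that correlate best with another tissue or exceed 100 M counts, counts thinned to the smallest total and libraries of 2 runs only in the hypothalamus, and no clock time term in brown fat. Other splits of the libraries exchanged the feeding labels within clock times, 21 with the real one. Tables were handled in Python 3.11.15.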

Results

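Polyadenylated RNA was sequenced from 22 tissues of C57BL/6J mice kept for 7 weeks on a Western diet (45% fat, 17% sucrose). Mice either ate without restriction (ad-libitum feeding, ALF) or had food from ZT13 to ZT22 (time-restricted feeding, TRF). ZT counts hours from lights on. Tissues were taken every 2 h at 12 clock times. The table held 1035 libraries, 517 of ALF and 518 of TRF, from 1677 sequencing samples. Of the 528 groups defined by tissue, feeding and clock time, 507 had 2 libraries and 21 had 1. Total counts per library ran from 2.26 to 501 M with a median of 11.3 M. Median totals were lowest in the kidney medulla in ALF (4.49 M) and in the kidney cortex in TRF (4.50 M), and highest in the hypothalamus, where they differed between the groups (39.1 M in ALF, 22.5 M in TRF). The ribosomal RNA gene Rn45s took a median of 16.9% of the counts in ALF and 17.5% in TRF in the suprachiasmatic nucleus (SCN). The labels do not state that replicates were separate animals, so every p-value measures only the spread between these libraries. Each library is bulk tissue, so a change in cell types or in the tissue dissected cannot be told from a change of expression within cells.

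The first comparison asks which genes sat at a different mean level over the day in TRF than in ALF. The white fat depots led: 9736 of 14609 genes changed in inguinal white fat (iWAT), 5152 up and 4584 down, and 8470 of 14132 in epididymal white fat (eWAT), 4360 up and 4110 down. Jejunum (6795), duodenum (6203), hypothalamus (5203), adrenal gland (4705), heart (4163), stomach (3790), skeletal muscle (3668) and liver (2605) followed. Spleen (1546), ileum (1455), kidney cortex (1381), pancreas (1018), lung (383) and kidney medulla (376) had fewer. The dentate gyrus (DG) had 26, the amygdala, arcuate nucleus and SCN 1 each, and brown fat (BAT) and the dorsomedial hypothalamus (DMH) 0. Over all tissues 61526 of 306020 tests passed at an adjusted p under 0.05, 31300 higher and 30226 lower in TRF (edgeR quasi-likelihood with Benjamini-Hochberg). Of these, 12013 also moved by at least 0.5 on the log2 scale.

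Part of these counts ran with base composition. The log2 fold changes correlated across genes with GC content in the jejunum (Spearman 0.700), stomach (0.588) and lung (0.515), and inversely in the duodenum (-0.696), hypothalamus (-0.646), brown fat (-0.600) and ileum (-0.458), but not in the liver (0.019). Genes are not independent replicates in such a correlation. With offsets that remove each library's trend with GC content, 2622 genes passed in the duodenum, 1960 in the hypothalamus, 3036 in the jejunum, 1740 in the stomach, 809 in the ileum, 234 in the lung and 2177 in the kidney cortex. Of these, 1769, 1371, 2191, 1239, 625, 175 and 1337 had passed in the same direction without offsets, while 50 in the duodenum, 43 in the hypothalamus and 43 in the jejunum passed in the opposite direction. Genes given below with a fold change and its error passed with these offsets too, except where the adjusted p with offsets is given. This was not checked for the genes flagged for opposite directions in the windows, nor for Hspd1 and Pla2g5. The numbers of tissues in which a gene rose or fell were not redone with offsets.

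**Figure D1:**
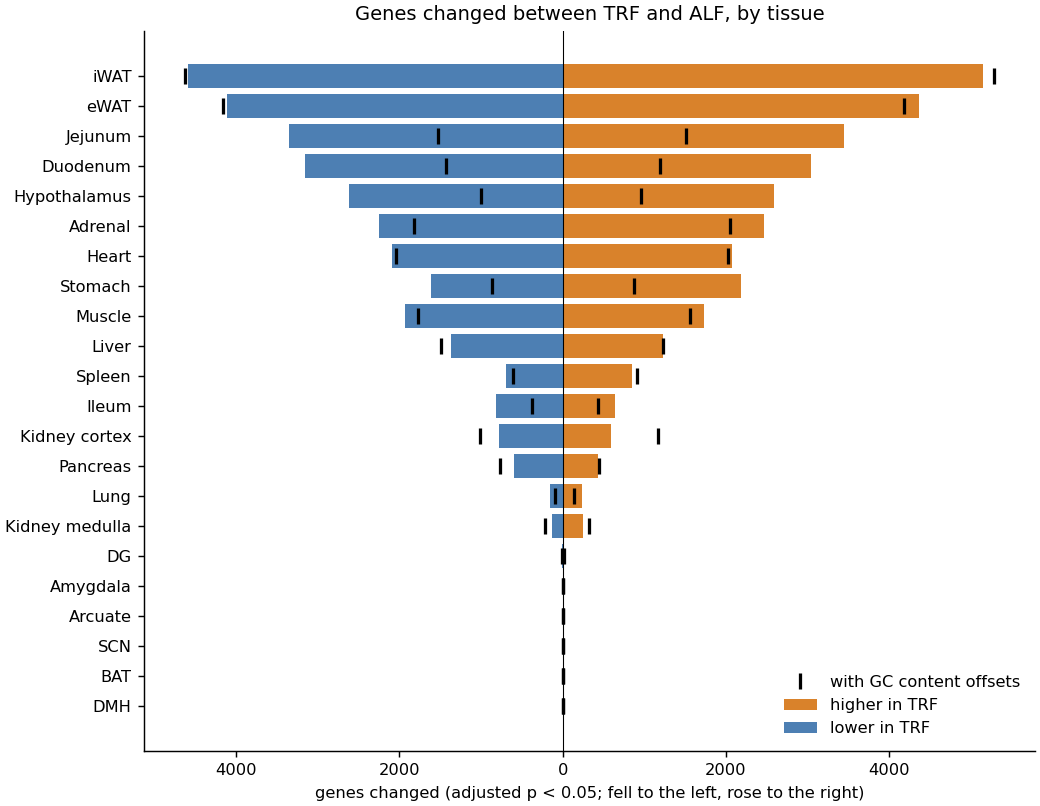
Number of genes higher (right) and lower (left) in TRF than in ALF at an adjusted p under 0.05 in each tissue, with black marks for the numbers after GC content offsets. Inguinal and epididymal white fat had 9736 and 8470 changed genes, and the marks of jejunum, duodenum and hypothalamus sit well inside their bars.

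Some genes moved the same way in many tissues. Heat shock proteins led the rises, with Hspd1, the mitochondrial chaperonin, up in 12 tissues by 0.13 to 0.45 (log2) and Hsp90ab1, a cytosolic HSP90, up in 12 by 0.18 to 0.52. Oas2, an interferon-induced antiviral enzyme, rose in 12 tissues, most in iWAT (0.88 ± 0.12 SE, n = 24 and 24 libraries, adjusted p = 2.8e-07). Cfd, which encodes the adipocyte-secreted protease adipsin (chromosome 10, 79890853 to 79892655, GRCm38), rose in 11 tissues by 0.78 to 2.74 and fell in the liver. Thrsp, a lipogenic nuclear protein, followed the same split, at 2.30 ± 0.33 in the ileum and -1.28 ± 0.30 in the liver. Lep, which encodes the adipocyte hormone leptin (chromosome 6, 29060220 to 29073877), fell in 10 of the 13 tissues where it was tested, from -1.15 in the jejunum to -2.91 in the adrenal gland. Npr3, the natriuretic peptide clearance receptor, and Pla2g5, a secreted phospholipase, each fell in 9 tissues. In all, 54 genes rose and 13 fell in 8 or more tissues, against means of 2.9 and 2.4 and maxima of 10 and 8 for random lists of the same sizes. Requiring a log2 fold change of at least 0.5 left 4 and 1. The tissues may come from the same mice, so they are not independent replicates. The random lists drew every tested gene alike. Genes that pass more readily in any tissue would thus raise such counts without a common response.

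In eWAT, genes of macrophages and inflammation were lower and genes of fatty acid synthesis higher in TRF (24 and 24 libraries). Of 29 macrophage and inflammation genes 28 fell and 1 did not pass (28 adjusted over the list alone), with a median log2 fold change of -1.62. The elastase Mmp12 fell by 3.59 ± 0.50, the monocyte chemokine Ccl2 by 2.98 ± 0.39 and its receptor Ccr2 by 1.42 ± 0.17, each lower in TRF at 11 of 12 clock times. All 9 antigen presentation genes of MHC class II fell (9 adjusted over the list alone), as did 22 of 24 extracellular matrix genes (22 adjusted over the list alone) while 1 rose. Fatty acid synthesis rose in 17 of 19 genes, with 2 not past the test (17 adjusted over the list alone), among them the acetyl-CoA carboxylases Acacb (2.05 ± 0.30) and Acaca (1.31 ± 0.21) and fatty acid synthase Fasn (0.94 ± 0.18). Tph2, known as the neuronal serotonin synthesis enzyme (chromosome 10, 115078641 to 115185022), fell by 5.09 ± 0.72 in eWAT and by 5.17 ± 0.54 in iWAT. The set test gave adjusted p = 1.5e-11 for macrophages, 4.5e-05 for MHC class II, 1.8e-06 for matrix and 5.0e-05 for fatty acid synthesis. With an estimated correlation none held (adjusted p = 0.672, 0.65, 0.673 and 0.65 with an estimated correlation). Adipocyte markers moved with these changes, as 11 of 14 rose and 1 fell (11 and 1 adjusted over the list alone; adjusted p = 0.0024, and adjusted p = 0.767 with an estimated correlation). Without replicate 1 the count of changed genes in eWAT was 2516.

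In iWAT the thermogenic uncoupling protein Ucp1 (chromosome 8, 83290352 to 83298452) rose by 5.21 ± 0.68, from a mean of 0.664 to 27.1 CPM (read counts scaled by library size), in 11 of 12 clock times. Single TRF libraries at ZT10 (333 CPM) and ZT22 (171 CPM) carried most of that mean, and the rise was 4.65 without ZT10. The thermogenesis list as a whole did not pass: 10 of its 16 genes rose and 5 fell (10 and 6 adjusted over the list alone), with a set test adjusted p = 0.441. Lep fell by 2.75 ± 0.35, the integrin Itgad by 5.30 ± 0.49 and Sparc, a matrix protein, by 1.35 ± 0.19. Interferon-stimulated genes rose in 24 of 25 (24 adjusted over the list alone), with Ifi44 at 1.10 ± 0.13 and Oas1a at 1.08 ± 0.14. All 20 markers of T and B lymphocytes rose (20 adjusted over the list alone; median 1.35), and 8 of 9 MHC class II genes rose while 1 fell (8 and 1 adjusted over the list alone). Extracellular matrix fell in 18 of 24 genes and rose in 2 (18 and 2 adjusted over the list alone), with Col4a2 at -1.52 ± 0.19. Set test adjusted p was 3.5e-08, 1.7e-05, 0.031 and 0.00015 for these lists, against adjusted p = 0.672, 0.809, 0.837 and 0.809 with an estimated correlation. Adipocyte markers fell in 10 of 14 and rose in 2 (10 and 2 adjusted over the list alone; adjusted p = 0.0302, and adjusted p = 0.837 with an estimated correlation). In the feeding window macrophage genes rose in 16 of 29 and fell in 4 (16 and 4 adjusted over the list alone; adjusted p = 0.0264, and adjusted p = 0.789 with an estimated correlation). Skeletal muscle fibre genes rose in 13 of 15 in the same libraries (13 adjusted over the list alone; median 2.68; adjusted p = 0.0011, and adjusted p = 0.837 with an estimated correlation). Whether the lymphocyte, MHC class II, interferon and muscle fibre rises came from the cells or tissue dissected was not tested. Leaving out replicate 1 gave 1733 changed genes in iWAT, and 4 ALF libraries correlated best with the mean profile of eWAT.

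The liver lowered genes of fatty acid synthesis. The list fell in 18 of 19 genes with 1 not past the test (19 adjusted over the list alone; median -0.78), led by stearoyl-CoA desaturase Scd1 (chromosome 19, 44394455 to 44407879; -1.95 ± 0.28) and malic enzyme Me1 (-1.74 ± 0.22). The set test gave adjusted p = 1.6e-15, and adjusted p = 0.332 with an estimated correlation. Cidec, a lipid droplet protein, fell by 2.55 ± 0.38 and Pparg, the adipogenic nuclear receptor, by 1.56 ± 0.19. Xenobiotic metabolism fell in 15 of 20 genes and rose in 1 (16 and 1 adjusted over the list alone; adjusted p = 2.8e-11, and adjusted p = 0.404 with an estimated correlation), with the cytochrome P450 Cyp2b9 at -5.32 ± 0.78 and Cyp2c29 at -1.28 ± 0.11, lower at 12 of 12 clock times. Targets of PPAR-alpha fell in 13 of 29 genes and 16 did not pass (17 fell adjusted over the list alone; adjusted p = 2.6e-05, and adjusted p = 0.789 with an estimated correlation). Among them were the fatty acid hydroxylase Cyp4a14 (-3.27 ± 0.63) and the fasting hormone Fgf21 (-1.71 ± 0.29). Acute phase genes rose in 17 of 19 (18 adjusted over the list alone; adjusted p = 4.6e-11, and adjusted p = 0.65 with an estimated correlation), with serum amyloid Saa1 at 3.65 ± 0.73 and Saa2 at 4.16 ± 0.92, fibrinogen alpha Fga at 0.97 ± 0.18 and hemopexin Hpx at 1.02 ± 0.20. Markers of cell types moved too: adipocyte genes fell in 4 of 8 (4 adjusted over the list alone; adjusted p = 0.0045, and adjusted p = 0.65 with an estimated correlation). Hepatocyte genes rose in 7 of 13 and fell in 1 (8 and 2 adjusted over the list alone; adjusted p = 0.0031, and adjusted p = 0.65 with an estimated correlation). Saa1 and Saa2 passed neither without replicate 1 nor without replicate 2, and the count of changed genes in the liver was then 517 and 873.

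Both kidney regions raised genes of fatty acid oxidation in TRF. In the cortex 22 of 27 PPAR-alpha targets rose and 5 did not pass (23 adjusted over the list alone; median 0.32; adjusted p = 3.9e-24, and adjusted p = 0.307 with an estimated correlation). In the medulla 18 of 27 rose (19 adjusted over the list alone; median 0.31; adjusted p = 1.3e-30, and adjusted p = 0.134 with an estimated correlation). Cyp4a14 (chromosome 4, 115486200 to 115496142), the fatty acid hydroxylase that fell in the liver, rose by 2.25 ± 0.39 in the cortex and by 1.95 ± 0.34 in the medulla (24 and 24 libraries each). Acadm, the medium-chain acyl-CoA dehydrogenase, rose by 0.40 ± 0.06 and 0.65 ± 0.07, at 12 of 12 clock times in both regions. The carnitine carrier Slc25a20 rose by 0.38 ± 0.05 in the cortex and the peroxisomal enzyme Ehhadh by 0.71 ± 0.10 in the medulla. The carboxylesterase Ces1g fell in both regions, by 1.76 ± 0.26 in the cortex, and in the medulla the prolactin receptor Prlr fell by 1.54 ± 0.34. Adipocyte markers rose in 1 of 5 in the cortex (2 adjusted over the list alone; adjusted p = 0.0464, and adjusted p = 0.65 with an estimated correlation). As sets, macrophage genes passed downward in the cortex and upward in the medulla, and MHC class II genes passed downward in both. None of these held with an estimated correlation. Without replicate 1 the counts of changed genes were 7 in the cortex and 0 in the medulla (246 up and 130 down with all libraries). In the medulla, 4 libraries correlated best with the cortex and the count without them was 612.

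Genes of fatty acid synthesis were higher in the jejunum in TRF. There Scd1 rose by 1.74 ± 0.17 and Fasn by 1.28 ± 0.12, at 12 of 12 clock times, and 15 of 19 fatty acid synthesis genes rose (15 adjusted over the list alone; adjusted p = 4.1e-07, and adjusted p = 0.332 with an estimated correlation). The C-type lectins Reg3b and Reg3g fell by 2.26 ± 0.28 and 1.75 ± 0.22, lower at 12 of 12 clock times. Lipid absorption and intestinal transport fell in 11 of 21 genes (median -0.21; adjusted p = 0.041, and adjusted p = 0.864 with an estimated correlation), with the cholesterol transporter Npc1l1 at -0.35 ± 0.09 and the peptide transporter Slc15a1 at -0.70 ± 0.15. In the duodenum the chitinase Chia1 fell by 4.54 ± 0.65 and Scd1 rose by 1.58 ± 0.31. In the ileum Saa1 fell by 2.21 ± 0.56, and 4 of 9 MHC class II genes fell (8 adjusted over the list alone; adjusted p = 0.00035, and adjusted p = 0.65 with an estimated correlation). Adipocyte markers rose in the same libraries. In the jejunum 10 of 14 adipocyte genes rose and 1 fell (adjusted p = 0.0027, and adjusted p = 0.672 with an estimated correlation), with Cfd at 2.33 ± 0.29. The ileum raised 9 of 14 and none fell (10 rose and 1 fell adjusted over the list alone; adjusted p = 1.1e-05, and adjusted p = 0.65 with an estimated correlation), with Cfd at 2.74 ± 0.42. Erythroid and matrix genes rose too, in 6 of 9 and 14 of 24 in the jejunum (6 and 15 adjusted over the list alone; adjusted p = 0.0379 and 0.0013, and adjusted p = 0.827 and 0.837 with an estimated correlation) and in 1 of 9 and 1 of 23 in the ileum (6 and 0 adjusted over the list alone; adjusted p = 0.0312 and 0.0083, and adjusted p = 0.807 and 0.849 with an estimated correlation). The ileum count was 0 without replicate 1 and 288 with the number of runs as a term.

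Genes of striated muscle were higher in the stomach libraries in TRF. Skeletal muscle fibre genes rose in 11 of 12 with 1 not past the test (12 adjusted over the list alone; median 1.47; adjusted p = 7.9e-06, and adjusted p = 0.65 with an estimated correlation), among them skeletal actin Acta1 (2.75 ± 0.62) and creatine kinase Ckm (1.07 ± 0.23, 12 of 12 clock times). Markers of mammary and epididymal epithelial cells rose in 6 of 9 genes (8 adjusted over the list alone; adjusted p = 0.00097, and adjusted p = 0.65 with an estimated correlation). Erythroid genes rose in 6 of 8 in the stomach (6 adjusted over the list alone; adjusted p = 0.0312, and adjusted p = 0.837 with an estimated correlation). Lep fell by 2.06 ± 0.33 and Npr3 by 1.20 ± 0.17. Without replicate 2 the stomach had 249 changed genes.

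The heart raised nuclear receptors of the immediate early class and stress proteins. Nr4a3 rose by 2.31 ± 0.19 at 12 of 12 clock times and Nr4a1 by 0.71 ± 0.13, and 9 of 19 immediate early genes rose with 10 not past the test (10 adjusted over the list alone; adjusted p = 0.00056, and adjusted p = 0.65 with an estimated correlation). Cytosolic heat shock proteins rose in 16 of 20 genes (17 adjusted over the list alone; adjusted p = 3.5e-08, and adjusted p = 0.65 with an estimated correlation). Interferon-stimulated genes rose in 19 of 25 (21 adjusted over the list alone; adjusted p = 3.9e-08, and adjusted p = 0.65 with an estimated correlation), with Oas2 at 0.58 ± 0.08. The metallothionein Mt2 rose by 1.45 ± 0.21. Acadm fell by 0.24 ± 0.03, and PPAR-alpha targets split, with 11 of 25 down and 3 up (11 and 3 adjusted over the list alone). Their median was -0.02 and their mean 0.00, while the set test read down (adjusted p = 0.032, and adjusted p = 0.849 with an estimated correlation). Cell-type lists moved in the heart as well: adipocyte genes rose in 4 of 6, macrophage genes in 14 of 26 and matrix genes in 12 of 24 with 1 down, while MHC class II fell in 2 of 8 (4, 16, 15 with 1 down, and 5 adjusted over the list alone). Set test adjusted p was 0.0187, 0.00033, 8.1e-05 and 0.0324, against adjusted p = 0.65, 0.673, 0.694 and 0.831 with an estimated correlation. Myl4, an atrial myosin light chain, fell by 1.18 ± 0.38. In skeletal muscle, macrophage genes rose in 14 of 23 (median 0.51; adjusted p = 3.9e-07, and adjusted p = 0.673 with an estimated correlation), with the complement gene C1qa at 0.57 ± 0.12. The adipocyte genes Cfd (1.10 ± 0.25) and Lep (-1.75 ± 0.40) went opposite ways in muscle. Muscle had 0 changed genes without replicate 1, and 1843 with the number of runs as a term.

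In the adrenal gland, neuropeptide genes rose: Cartpt by 2.23 ± 0.25, Npy by 1.68 ± 0.22 and galanin (Gal) by 1.36 ± 0.18, each at 12 of 12 clock times. Of 6 feeding and sleep neuropeptides 4 rose and 2 did not pass (4 adjusted over the list alone; adjusted p = 0.0017, and adjusted p = 0.65 with an estimated correlation). Vgf, a neuroendocrine secretory protein, rose by 2.47 ± 0.41. Elovl6, a fatty acid elongase, rose by 0.82 ± 0.12 and Acaca by 0.88 ± 0.15, as 12 of 19 fatty acid synthesis genes rose and 1 fell (13 and 2 adjusted over the list alone; adjusted p = 0.00063, and adjusted p = 0.682 with an estimated correlation). Lep fell by 2.91 ± 0.33. Of 14 steroid synthesis genes 1 rose, 2 fell and 11 did not pass (set test adjusted p = 0.845). Cell-type lists fell in the same libraries: MHC class II in 8 of 8 genes, lymphocytes in 6 of 9, proliferation in 12 of 25, macrophages in 13 of 28 with 3 up, and matrix in 11 of 24 with 1 up (8, 6, 13, 15 and 13 fell, and 0, 0, 0, 3 and 1 rose, adjusted over the list alone). Their set tests gave adjusted p = 4.5e-05, 0.006, 7.8e-05, 0.00076 and 0.00023, against adjusted p = 0.65, 0.65, 0.65, 0.767 and 0.694 with an estimated correlation. In the feeding window adipocyte genes fell in 6 of 14 and muscle fibre genes rose in 6 of 6 (6 and 6 adjusted over the list alone; adjusted p = 0.00089 and 0.034, and adjusted p = 0.678 and 0.716 with an estimated correlation). Without replicate 1 the adrenal count was 488.

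The spleen raised genes of cell division. The neutrophil protease Prtn3 rose by 2.94 ± 0.46 and ficolin B (Fcnb) by 2.93 ± 0.45 (23 ALF and 21 TRF libraries). Proliferation genes rose in 18 of 25 (24 adjusted over the list alone; median 0.51; adjusted p = 1.3e-14, and adjusted p = 0.65 with an estimated correlation), with the mitotic kinase Aurka at 0.80 ± 0.18 and Mcm2 at 0.51 ± 0.12. T and B lymphocyte markers fell in 3 of 20 and 17 did not pass (7 fell adjusted over the list alone; adjusted p = 0.00034, and adjusted p = 0.694 with an estimated correlation). Pancreatic acinar markers read higher in the spleen as a set, with 0 of 23 past the test over all genes or adjusted over the list alone (median 0.95; adjusted p = 0.0027, and adjusted p = 0.85 with an estimated correlation). In the lung 16 of 24 matrix genes rose (18 up and 1 down adjusted over the list alone; adjusted p = 1.7e-14, and adjusted p = 0.332 with an estimated correlation), with the collagens Col3a1 at 0.50 ± 0.07 and Col1a1 at 0.62 ± 0.10, at 12 of 12 clock times. Erythroid genes rose in 2 of 11 in the lung (11 adjusted over the list alone; adjusted p = 3.5e-06, and adjusted p = 0.65 with an estimated correlation). As sets, smooth muscle genes also passed upward in the lung, and lymphocyte and MHC class II genes downward. None of these held with an estimated correlation, and the smooth muscle call was lost with GC offsets. In the pancreas digestive enzyme genes were lower: 7 of 25 acinar genes fell and 18 did not pass (22 fell adjusted over the list alone; median -0.74; adjusted p = 7.2e-13, and adjusted p = 0.65 with an estimated correlation). Syncollin (Sycn) fell by 1.17 ± 0.22 and colipase (Clps) by 0.96 ± 0.23. Cfd rose by 1.91 ± 0.44 (24 and 22 libraries). As sets, macrophage genes also passed upward in the pancreas. Markers of mammary and epididymal epithelium and of choroid plexus and ependyma passed downward there. None of these held with an estimated correlation, and the macrophage call was lost with GC offsets. Without replicate 2 the spleen and pancreas counts were 0 and 0, and the lung count was 1 without replicate 1.

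Few genes passed the test in brain regions apart from the whole hypothalamus, which does not show that little changed. By edgeR 1490 of 14191 genes in the amygdala and 1522 of 13426 in the dentate gyrus had an unadjusted p under 0.05. In the whole hypothalamus the stress chaperone Hsp90aa1 rose by 0.43 ± 0.05, with 16 of 20 cytosolic heat shock genes up (16 adjusted over the list alone; adjusted p = 4.7e-10, and adjusted p = 0.65 with an estimated correlation; 22 and 24 libraries). In the dentate gyrus the synaptic pentraxin Nptx2 rose by 0.84 ± 0.16 and the chaperone Hsph1 by 0.42 ± 0.07, while Cntln fell by 0.43 ± 0.07. The 1 gene past the test in the arcuate nucleus was Pcsk1n, a prohormone convertase inhibitor (0.68 ± 0.12, adjusted p = 0.034). In the SCN it was the astrocyte filament Gfap (0.75 ± 0.14, adjusted p = 0.037, and 0.0681 with GC offsets), and in the amygdala Mboat7 (0.19 ± 0.04, adjusted p = 0.044, and 0.305 with GC offsets). In the dorsomedial hypothalamus edgeR called 0 of 14510 genes, with 833 at an unadjusted p under 0.05 and 0 by DESeq2. The heat shock list there had 0 members past the test over all genes and 15 of 20 higher adjusted over the list alone (adjusted p = 2.3e-20, and adjusted p = 0.134 with an estimated correlation). Adipocyte markers moved in the SCN libraries too, with 0 of 14 past the test over all genes and 2 higher adjusted over the list alone (adjusted p = 5.4e-05, and adjusted p = 0.65 with an estimated correlation). Without ZT2 the counts of arcuate nucleus, SCN and amygdala were each 0, and the dentate gyrus count ran from 0 without replicate 1 to 209 without replicate 2.

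Brown fat gave 0 changed genes of 13309 by edgeR and 0 by DESeq2, with 1702 at an unadjusted p under 0.05. All 17 thermogenesis genes were short of the test (median -0.13; adjusted p = 0.02 downward, and adjusted p = 0.703 with an estimated correlation). As sets, skeletal muscle fibre genes passed upward in the same libraries, and erythroid and macrophage genes downward. None of these held with an estimated correlation. Clock genes of the brown fat libraries did not follow the labelled clock times: 37 of 48 libraries read over 5 h from their label by their clock gene levels. The reading used the mean ALF peak times of the other tissues outside the brain. In the SCN 32 of 45 libraries read over 5 h from their label, but only 1 lay over 5 h from a common shift of 6.44 h. The SCN libraries thus followed their labels with an offset. Also over 5 h off were 7 libraries in the arcuate nucleus, and 6 each in the dentate gyrus and dorsomedial hypothalamus. There were 4 in the amygdala, 2 in the spleen, and 1 each in the pancreas and stomach. Without a clock time term the count of changed genes in brown fat was also 0. The feeding labels of these libraries come from the same names as the clock times and were not checked. The 0 therefore does not show that feeding left brown fat unchanged.

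**Figure D2:**
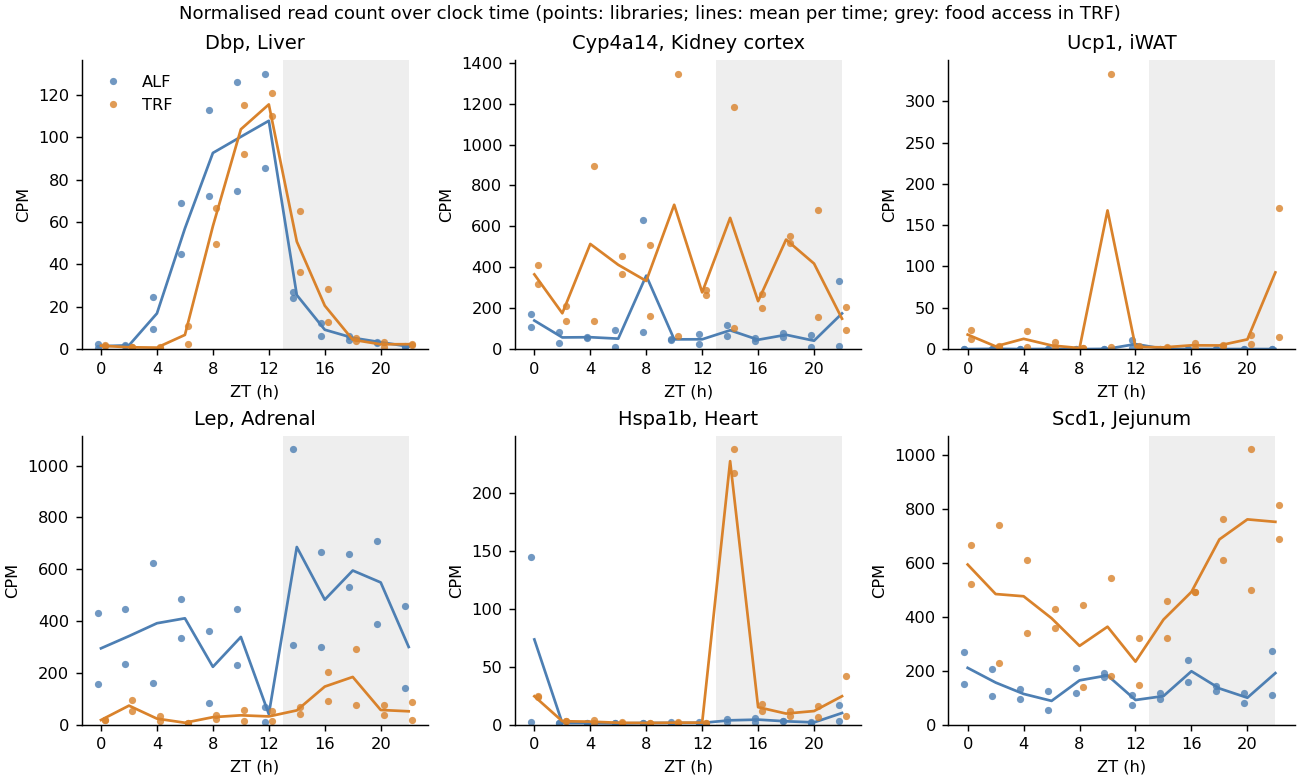
Normalised read count (CPM, vertical axes) over clock time (ZT in h) of Dbp in liver, Cyp4a14 in kidney cortex, Ucp1 in iWAT, Lep in the adrenal gland, Hspa1b in heart and Scd1 in jejunum, with a point per library, a line through the mean per time and grey for food access in TRF. Mean Lep in the adrenal gland was 388 CPM in ALF and 59.7 CPM in TRF, and Hspa1b in heart parted the groups mainly at ZT14 (217 and 237 CPM in TRF), with an ALF library at ZT0 of 145 CPM.

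The second comparison separates the hours of food access in TRF (ZT14 to ZT22 among the sampled times) from the fast (ZT0 to ZT12). In the feeding window the inducible HSP70 gene Hspa1b (chromosome 17, 34956436 to 34959238) rose by 2.84 ± 0.53 in the heart and by 2.01 ± 0.45 in muscle. Over the whole day its rise of 1.37 ± 0.46 in the heart missed the test without ZT14 (0.66) or ZT20 (1.25). Cytosolic heat shock proteins passed upward in 21 of 22 tissues, and in 0 with an estimated correlation. They rose in 19 of 20 in the heart (19 adjusted over the list alone; adjusted p = 1.7e-15, and adjusted p = 0.427 with an estimated correlation) and in 19 of 20 in muscle (adjusted p = 8.8e-16, and adjusted p = 0.349 with an estimated correlation). In the liver the endoplasmic reticulum chaperones rose in 19 of 24 (19 up and 1 down adjusted over the list alone; median 0.89; adjusted p = 1.6e-12, and adjusted p = 0.536 with an estimated correlation), with Hsp90b1 at 1.32 ± 0.19. Liver squalene epoxidase Sqle rose by 1.12 ± 0.22 in this window. The cholesterol synthesis list of the liver rose in 6 of 24 genes and fell in 2 here (11 and 2 adjusted over the list alone; adjusted p = 0.0214, and adjusted p = 0.828 with an estimated correlation), but fell in 13 in the fasting window (18 adjusted over the list alone; adjusted p = 2.5e-14, and adjusted p = 0.76 with an estimated correlation) and in 4 over the day (3 adjusted over the list alone; adjusted p = 0.0174, and adjusted p = 0.849 with an estimated correlation). In the feeding window ribosome biogenesis genes rose in 18 of 29 (22 adjusted over the list alone; adjusted p = 3.2e-10, and adjusted p = 0.41 with an estimated correlation). In eWAT the endoplasmic reticulum chaperones went the other way, with 19 of 24 down and 1 up (20 and 1 adjusted over the list alone; adjusted p = 2.5e-07, and adjusted p = 0.588 with an estimated correlation). The muscle atrophy ligases Fbxo32 and Trim63 fell by 1.28 ± 0.20 and 0.73 ± 0.12 in skeletal muscle, where 5 of 17 FOXO targets fell and 1 rose (8 and 1 adjusted over the list alone; adjusted p = 0.0011, and adjusted p = 0.537 with an estimated correlation).

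In the fasting window, PPAR-alpha targets passed upward in 12 tissues and downward in brown fat, whose clock labels are in doubt, and in 0 with an estimated correlation. Pdk4, the kinase that limits pyruvate oxidation, rose by 1.85 ± 0.33 in the kidney cortex and by 1.03 ± 0.20 in the lung. In the kidney cortex 17 of 27 targets rose (24 adjusted over the list alone; adjusted p = 2.1e-27, and adjusted p = 0.32 with an estimated correlation), and in the pancreas 11 of 24 (19 adjusted over the list alone; adjusted p = 2.2e-11, and adjusted p = 0.76 with an estimated correlation). Over all tissues 34603 tests passed in the fasting window and 45180 in the feeding window. The difference between the windows itself passed in 2897 tests, most in the liver (972), jejunum (954) and eWAT (345), and 295 of them had passed in opposite directions in the windows. Without replicate 1 or 2 these differences numbered 11 or 14, and DESeq2 gave 4703.

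**Figure D3:**
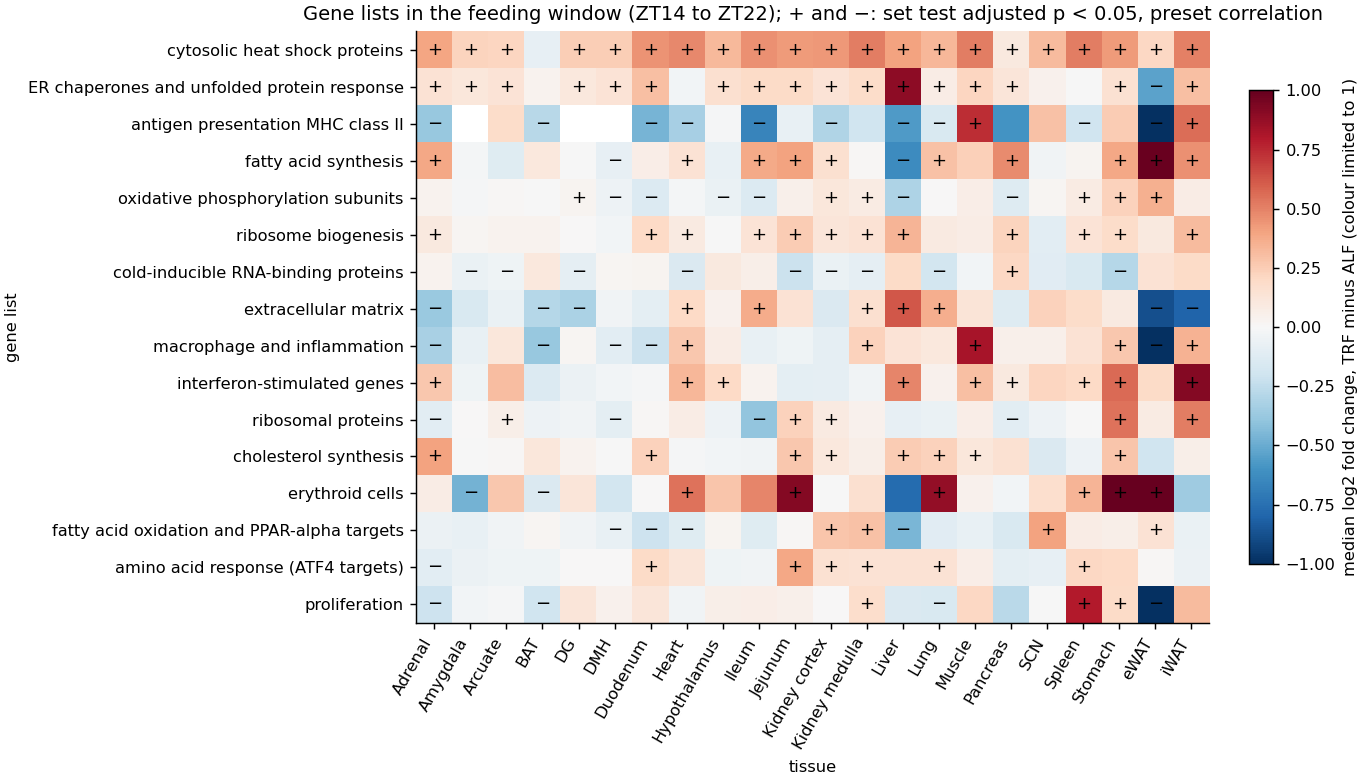
Median log2 fold change in the feeding window (colour, TRF minus ALF, limited to 1) of the 16 gene lists with the most calls in each of 22 tissues, with signs where the set test had an adjusted p under 0.05 at its preset correlation. Cytosolic heat shock proteins carry a plus sign in 21 tissues, and none of the calls in this window held with an estimated correlation.

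The third comparison asks how the daily rhythm differed. In TRF 85748 gene and tissue combinations had a 24-h rhythm, against 37877 in ALF, and 26909 were rhythmic in both. The ileum (567 in ALF, 6713 in TRF), jejunum (2206, 8436), adrenal gland (1725, 5716) and muscle (1957, 5854) showed the widest gaps, while the lung had fewer in TRF (6464, 5956). Numbers past a threshold in each group do not test the difference. In the ileum a random exchange of the feeding labels gave 6728 rhythmic genes in its ALF group and 1030 in its TRF group. Tested directly, the rhythm differed in 5738 combinations, with the larger amplitude in TRF in 4894 and in ALF in 844. Most lay in eWAT (1726), liver (1139), jejunum (977) and heart (732), while the ileum had 7. With an amplitude of at least 0.25 (log2) required, 52354 in TRF and 22727 in ALF were left. Without replicate 1 or 2 the rhythm differences numbered 916 or 424. Of 20 random exchanges of the feeding labels, 1 gave more (6550), so chance cannot be excluded for this total. That exchange was carried by iWAT (5585), while no exchange gave over 6 in eWAT, jejunum or heart, or over 954 in the liver.

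Core clock genes peaked later in TRF in most peripheral tissues. In the liver all 20 clock genes rhythmic in both groups peaked later, by a median of 1.93 h, and 17 differed in rhythm adjusted over the list alone (16 over all genes). Liver Dbp, a clock output factor, peaked at 10.1 ± 0.295 h in ALF and at 12.0 ± 0.282 h in TRF, and the repressor Per2 moved from 13.4 ± 0.463 to 17.0 ± 0.232 h. In the kidney cortex the median delay was 1.94 h with 16 genes past the test adjusted over the list alone (12 over all genes). The delay was 1.20 h in the adrenal gland, 1.18 h in the heart, 1.24 h in the ileum and 1.07 h in muscle. There 12, 15, 8 and 8 genes differed in rhythm adjusted over the list alone (4, 8, 0 and 3 over all genes). The median shift was 0.382 h in eWAT and 0.057 h in iWAT, and 0.594 h in the pancreas and 0.683 h in the stomach. In these 15, 10, 0 and 3 differed (7, 8, 0 and 1 over all genes). The test takes amplitude and peak time together, so no delay was tested by itself. Amplitudes were larger in TRF by a median of 0.39 in eWAT and 0.43 in iWAT (log2), and by 0.34 in the liver. Tissues were not tested against each other. Nr1d1, a nuclear receptor of the clock, had an amplitude of 1.73 ± 0.15 in ALF and 2.48 ± 0.15 in TRF in eWAT. Dbp was rhythmic in both groups in all 21 tissues other than brown fat, and peaked later in TRF in 20. Bhlhe40, a feeding-responsive repressor, moved most, by a median of 2.97 h over 9 tissues. In the SCN 9 clock genes were rhythmic in both groups and 0 of 21 differed in rhythm by edgeR, adjusted over the list alone or over all genes (760 of all genes at an unadjusted p under 0.05). Brown fat had 0 rhythmic clock genes in either group by the labelled times. Its clock gene levels did not follow those labels, so the 0 does not show a lost rhythm. Summed over tissues, 135 clock gene rhythms differed adjusted over the list alone, and 40 and 93 without replicate 1 and 2. As a set, the clock list's mean level passed in none of the 22 tissues, with a lowest adjusted p of 0.0891 (limma camera). With GC offsets it passed downward in 2 tissues (spleen and stomach). It passed downward in 5 tissues in the fasting window and upward in 2 in the feeding window (8 and 3 with GC offsets), and in 0 with an estimated correlation.

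**Figure D4:**
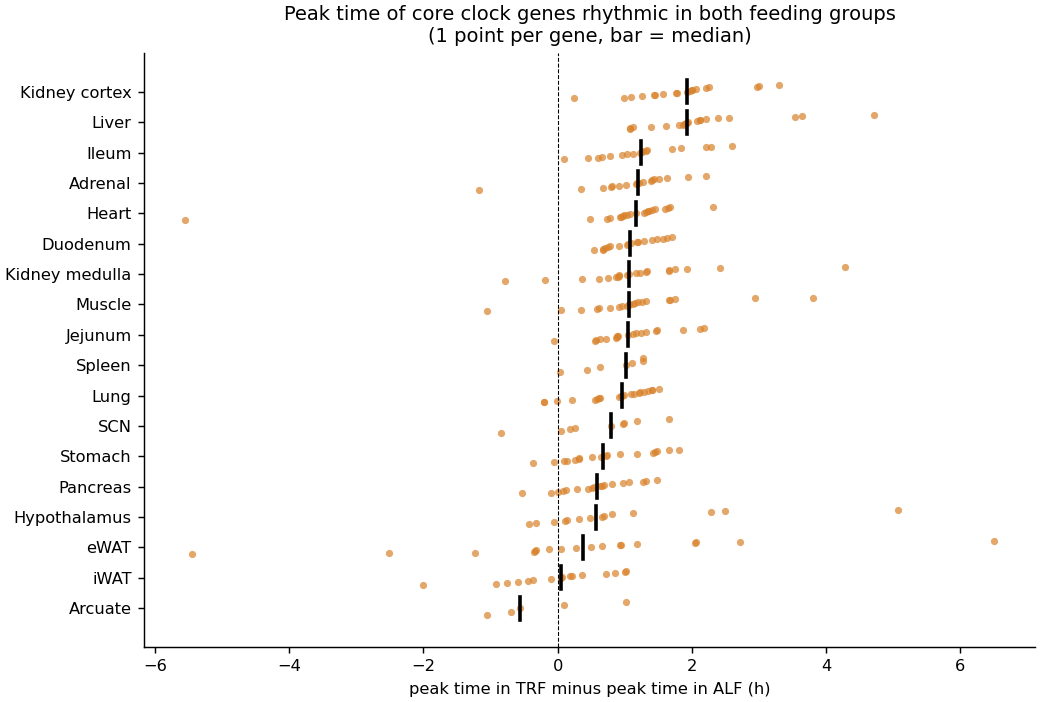
Peak time in TRF minus peak time in ALF (h) of core clock genes rhythmic in both groups, a point per gene and a bar at the median, for tissues with at least 5 such genes. Liver and kidney cortex sit furthest to the right with medians of 1.93 and 1.94 h, and iWAT sits at 0.057 h.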

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

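The tests on brown fat, the thinned counts, libraries of 2 runs and GC offsets in the hypothalamus, and the overlap of splits with the real labels were chosen after the results were seen, and the other tests in this part were set beforehand. In 10 tissues a gene moved one way in the fasting window and the other way in the feeding window, with a test of the difference past the threshold, and in each tissue the one with the smallest p of the difference is given (log2 difference, feeding minus fasting). Angptl4, a fasting-induced lipase inhibitor, differed by -1.37 in the adrenal gland, where it rose by 0.75 ± 0.14 in the fast and fell by 0.62 ± 0.16 in the feeding window. Mthfd2, of mitochondrial folate metabolism, differed by 0.86 in the duodenum (-0.23 ± 0.09 and 0.63 ± 0.10). G0s2, an inhibitor of lipolysis, differed by 1.10 in the heart (-0.50 ± 0.09 and 0.60 ± 0.10). Heca differed by -0.63 in the jejunum (0.24 ± 0.06 and -0.39 ± 0.07). Npas2, a clock activator, differed by -1.58 in the kidney cortex (0.69 ± 0.16 and -0.89 ± 0.21). Glt28d2 differed by -1.29 in the liver (0.36 ± 0.11 and -0.93 ± 0.13). Tnfaip3, a brake on NF-kB signalling, differed by 0.96 in muscle (-0.35 ± 0.10 and 0.61 ± 0.13). Txnip, a glucose-responsive arrestin, differed by -0.63 in the stomach (0.32 ± 0.08 and -0.31 ± 0.10). Ppp1r3b, a glycogen-targeting phosphatase subunit, differed by 2.57 in eWAT (-0.80 ± 0.28 and 1.77 ± 0.33). Klf11 differed by -1.05 in iWAT (0.39 ± 0.10 and -0.66 ± 0.12). Among genes with a mean of at least 5 CPM, the numbers of such genes were 89 in the jejunum, 59 in the liver, 47 in eWAT, 27 in iWAT, 18 in the heart, 17 in the duodenum, 9 in the adrenal gland, 5 in the kidney cortex, 2 in muscle and 1 in the stomach.

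Counts also appear in the 4 left-out rows whose names read as dates. The rows named Mar-01 had means of 22.6 and 23.8 CPM, with counts in 1034 and 876 libraries, and those named Mar-02 had means of 68.3 and 172 CPM, with counts in 1035 libraries each. Which gene each belongs to is not known from the names.

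The clock genes of the brown fat libraries did not follow the labelled times, with 37 of 48 libraries over 5 h from their label (32 of 45 in the SCN, where 1 lay over 5 h from a common shift of 6.44 h). A shift common to all brown fat libraries is argued against, since 21 of the 48 lay over 5 h from the best common shift. A lost rhythm is argued against too, because the clock genes of a library were as coherent (median 0.745) as in the 15 other tissues outside the brain (0.502 to 0.762). Labels that do not belong to the libraries remain a candidate explanation: ALF and TRF libraries with the same label read times only 1.01 h apart (median of 48 pairs), against 1.2 h for 24 pairs within a group. No library was given another label, and no biological explanation other than a lost rhythm was tested. Whether the feeding labels belong to the brown fat libraries was not tested either.

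The hypothalamus had 5203 changed genes while the arcuate nucleus, SCN and dorsomedial hypothalamus had 1, 1 and 0, and its ALF libraries were deeper (medians of 39.1 and 22.5 M). With every library thinned to the smallest total 4032 genes passed, and among libraries of 2 runs 4118 passed, which argues against depth and the number of runs as the whole cause. GC content may account for a large part: with GC offsets 1371 of the calls were left in the same direction. An effect of feeding stays open and untested beside a GC trend that ran with the groups.

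Adipocyte genes moved in tissues other than fat, with Lep lower in 8 of these tissues. The test for fat tissue carried over to a lesser extent in TRF could not decide. It used 188 adipose-enriched genes, among them 13 of the 14 listed adipocyte markers. These genes were picked from these same libraries by high levels in both white fat depots against the other tissues. They include macrophage and matrix genes such as Mmp12, Ccl2 and Col6a2, so they do not measure adipocytes alone. In all 8 tissues the median fold of the adipose-enriched genes differed from the Lep fold by over 0.5 on the log2 scale. But Lep fell within fat itself, from a mean of 5930 to 2750 CPM in eWAT, so such a gap can arise either way. The medians ran from -0.26 in the adrenal gland to 0.18 in the jejunum. Carried-over fat whose own expression changed could account for the pattern, as Lep fell and Cfd rose in eWAT too. Its test was not decisive: the folds of these genes correlated with those in eWAT at a median Spearman of 0.212 (from -0.006 in the spleen to 0.551 in the adrenal gland). Expression of these genes by the tissue's own adipocytes, or by other cells, stays open, and levels of Adipoq were 7.96% of those in eWAT in the adrenal gland and 0.166% in the spleen.

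Feeding labels exchanged within clock times gave 21 splits with the real one. No other split reached the mean-level counts (real, then highest of the others) of the adrenal gland (4705, 130), dentate gyrus (26, 0), duodenum (6203, 1), heart (4163, 0), hypothalamus (5203, 1), ileum (1455, 0), jejunum (6795, 0), kidney medulla (376, 0), liver (2605, 0), lung (383, 1), muscle (3668, 0), pancreas (1018, 0), spleen (1546, 0), stomach (3790, 0), eWAT (8470, 5053) and iWAT (9736, 4665). That is 1 of 21 splits, the least a tissue can reach, with no adjustment over the 22 tissues. A real feeding difference also widens the spread within exchanged groups, which lowers their counts. Chance is thus made less likely in these tissues, not excluded. The single genes of the amygdala (1, 0) and arcuate nucleus (1, 0) were not matched by another split, but each count was 0 with some clock times left out, so chance is not taken as excluded there. It cannot be excluded for the kidney cortex (1381, 1438), where 2 of the 21 splits gave as many genes, nor for the SCN (1, 3), where 3 did. The splits decide nothing for brown fat (0, 0) and the dorsomedial hypothalamus (0, 1), because a real count of 0 by edgeR is reached by all 21, with 1702 and 833 genes at an unadjusted p under 0.05 and 0 in both by DESeq2. Summed over tissues, no other split reached the total of the 2 windows together (79783, 6243) or of the core clock rhythms (135, 13). For the total of genes whose rhythm differed (5738, 6550) chance cannot be excluded, as 2 of the 21 splits gave as many. The higher one was carried by iWAT (5585, against 402 with the real labels). No other split reached the real count in eWAT (1726, 0), jejunum (977, 6), heart (732, 4) or liver (1139, 954). Splits that called several times the real count of rhythm differences, in iWAT, the ileum (7, 1525), kidney medulla (6, 888), kidney cortex (160, 429), amygdala (1, 359) and brown fat (0, 51), point to a structure of the samples that was not tested. The highest other splits in eWAT, iWAT and the kidney cortex (5053, 4665 and 1438 genes) were among those nearest the real labels or their mirror image. They shared 34 of 48 labels with one of these. Heart, jejunum and liver also had splits with 34 of 48, yet no other split called a gene there. In the kidney cortex the split called more genes than the real labels. Overlap with the real labels thus does not account for these counts by itself, and their cause was not tested.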

How the results depend on the processing

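The GC offsets, the terms for the number of runs and for fractional counts, and the removal of libraries nearest another tissue or over 100 M counts were tests chosen after the results were seen, and the other settings were planned. DESeq2 size factors and the replicate block kept the total of 61526 genes within 1.5 times (61594 and 63752), as did no filter (61223), GC offsets (48113), DESeq2 (65046) and each clock time left out (53676 to 61990). The planned setting of the first run of each library was not run, since the table holds a single column per library. A term for fractional counts, tried in the ileum alone, gave 2032 genes. Among the counts that lead the comparisons, 390 values stayed within 1.5 times or on the same side, 21 were larger and 122 smaller. For the window and rhythm counts of single tissues these numbers were 683, 119 and 290. None of these counts turned direction, but with GC offsets single genes passed in the opposite direction (50 in the duodenum, 43 in the hypothalamus, 43 in the jejunum and 2 in eWAT). The named genes kept direction and call in 2190 values, with 133 no longer past the test and 1 newly past it.

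Leaving out replicate 1 or replicate 2 leaves 1 library in each group, which is assumed to vary like the other groups. Far fewer samples remain, so lower power is built into this setting. The results without replicate 1 and without replicate 2 also differed from each other, and which count was lower varied by tissue. Lower power need not be the only reason, and the cause was not tested. The mean-level total ran from 18699 to 35945 without a replicate, the fasting window (34603) from 5132 to 18718, the feeding window (45180) from 10688 to 17659, and the difference of windows (2897) from 11 to 14. Rhythms ran from 9071 to 9813 in ALF (37877), from 24281 to 42452 in TRF (85748) and from 424 to 916 for their difference (5738). Core clock differences (135) ran from 40 to 93. DESeq2 gave 4703 genes for the difference of windows. An amplitude of at least 0.25 left 22727 rhythms in ALF and 52354 in TRF, by its construction. For genes shared by 8 or more tissues, an adjusted p under 0.01 left 9 of 54 rises and 2 of 13 falls, and a log2 fold change of at least 0.5 left 4 and 1. With a correlation estimated per list, 0 of 225 list calls for the mean level, 0 of 192 in the fasting window and 0 of 243 in the feeding window held, while the replicate block gave 221, 189 and 242 and GC offsets gave 229, 208 and 244. The cause was not tested.

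Over replicates and clock times left out, the counts by tissue ran as follows: adrenal gland 488 to 4649 (4705 with all libraries), amygdala 0 to 10 (1), arcuate nucleus 0 to 15 (1), dentate gyrus 0 to 209 (26), duodenum 2484 to 6428 (6203), heart 1298 to 4495 (4163), hypothalamus 1878 to 5411 (5203), ileum 0 to 2629 (1455), jejunum 2629 to 6869 (6795), kidney cortex 7 to 1700 (1381), kidney medulla 0 to 655 (376), liver 517 to 3177 (2605), lung 1 to 627 (383), muscle 0 to 4145 (3668), pancreas 0 to 1191 (1018), SCN 0 to 1 (1), spleen 0 to 2186 (1546), stomach 249 to 4595 (3790), eWAT 2516 to 9099 (8470) and iWAT 1733 to 10256 (9736). The cause of the changes with single clock times was not tested. Counts that moved by over 1.5 times were, in the dentate gyrus, 48 without ZT0, 11 without ZT2, 17 without ZT4, 12 without ZT10 or ZT20, 15 without ZT18 and 144 without ZT22. In the ileum they were 774 without ZT0, 785 without ZT2, 2629 without ZT10, 612 without ZT14, 579 without ZT16, 601 without ZT20 and 821 without ZT22. In the kidney medulla they were 655 without ZT2, 218 without ZT4 and 217 without ZT6 or ZT20. In the lung they were 627 without ZT12, 135 without ZT14, 89 without ZT20 and 155 without ZT22, and in the pancreas 536 without ZT2, 524 without ZT6, 352 without ZT8 and 569 without ZT18. In the spleen they were 838 without ZT14, 714 without ZT16, 805 without ZT20 and 799 without ZT22, and in the stomach 2429 without ZT22. The single gene of the amygdala was lost (0) without ZT2, ZT4, ZT8, ZT12, ZT14, ZT18, ZT20 or ZT22, and 10 passed without ZT16. That of the arcuate nucleus was lost (0) without ZT2, ZT6, ZT8, ZT10, ZT14, ZT16, ZT18 or ZT22, with 3 genes without ZT4 and 15 without ZT12. That of the SCN was lost (0) without ZT2, ZT4, ZT10, ZT12, ZT16, ZT18, ZT20 or ZT22.

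With GC offsets the count moved by over 1.5 times in the duodenum (2622), hypothalamus (1960), ileum (809), jejunum (3036), stomach (1740), lung (234), kidney cortex (2177), SCN (0) and amygdala (0). The offsets remove a trend with GC content by construction, and whether that trend is technical was not tested. The replicate block gave 2196 genes in the ileum and 0 in the amygdala, and size factors gave 0 in the amygdala. Without a filter 11 genes passed in the amygdala, 6 in the arcuate nucleus, 25 in the SCN and 1 in the dorsomedial hypothalamus. DESeq2 gave 4 in the amygdala, 14 in the arcuate nucleus, 127 in the dentate gyrus, 760 in the lung and 0 in the SCN. The number of runs as a term gave 288 in the ileum and 1843 in muscle. Without the libraries nearest another tissue the arcuate nucleus had 0 and the kidney medulla 612, against 5719 in the duodenum, 1622 in the ileum and 8485 in iWAT. Without libraries over 100 M counts the lung had 365 and muscle 4135. The cause of these changes was not tested. Brown fat gave 0 by edgeR in each setting run and 0 by DESeq2, with 1702 genes at an unadjusted p under 0.05. In data simulated at the depth of 3 tissues the mean-level test found 59% (dorsomedial hypothalamus), 76% (brown fat) and 95% (liver) of changes of 0.5 on the log2 scale. Changes of that size or smaller can thus be missed where few genes passed. The simulated counts held no GC trend and no shared deviations, so the real shares may be lower.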

Other observations

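The test of shared deviations between tissues in this part was chosen after the result was seen, and the gene lists were planned. In the heart, RNA-binding proteins of the cold response fell in 6 of 12 genes with 6 not past the test (6 adjusted over the list alone), by a median of -0.10 (set test adjusted p = 0.015, and adjusted p = 0.65 with an estimated correlation). The splicing factor Srsf5 fell by 0.31 ± 0.08. With GC offsets the heart call was lost. The same list passed downward in 11 tissues and upward in 1, downward in 5 with GC offsets, and in 0 with an estimated correlation. In the heart the glucocorticoid targets rose in 5 of 15 genes (7 adjusted over the list alone; adjusted p = 0.024, and adjusted p = 0.807 with an estimated correlation), with the metallothionein Mt1 at 0.62 ± 0.10. Smooth muscle genes rose in 4 of 10 (5 adjusted over the list alone; adjusted p = 0.016, and adjusted p = 0.65 with an estimated correlation), with Acta2 at 0.71 ± 0.11. Erythroid genes rose in 6 of 11 in the heart (9 adjusted over the list alone; adjusted p = 0.0019, and adjusted p = 0.809 with an estimated correlation), with the anion exchanger Slc4a1 at 0.87 ± 0.22. In eWAT all 8 rose (8 adjusted over the list alone; adjusted p = 0.0013, and adjusted p = 0.762 with an estimated correlation), with the globin Hba-a1 at 0.97 ± 0.19.

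The liver raised interferon-stimulated and matrix genes. Of 25 interferon-stimulated genes 12 rose, 1 fell and 12 did not pass (13 and 1 adjusted over the list alone; median 0.28; adjusted p = 1.4e-05, and adjusted p = 0.673 with an estimated correlation), with Oas1a at 0.72 ± 0.13 and Isg15 at 0.52 ± 0.13. The adrenal gland raised 14 of 25 (14 adjusted over the list alone; adjusted p = 0.00029, and adjusted p = 0.807 with an estimated correlation), with Ifit1 at 0.62 ± 0.10. Matrix genes rose in 16 of 22 in the liver (16 up and 1 down adjusted over the list alone; median 0.42; adjusted p = 3.4e-08, and adjusted p = 0.65 with an estimated correlation), with Col6a2 at 0.62 ± 0.11 and lumican (Lum) at 0.46 ± 0.10. In the dentate gyrus during the feeding window, 0 of 19 immediate early genes passed over all genes by edgeR and 9 rose adjusted over the list alone (median 0.51; adjusted p = 1.2e-08, and adjusted p = 0.183 with an estimated correlation).

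Libraries with the same label deviated together in different tissues. Each library was scored on the 100 genes with the smallest p in its tissue, for 16 tissues with enough changed genes, and the score of replicate 1 minus replicate 2 was compared between tissues over the feeding groups and clock times. Over 120 pairs of tissues the median Pearson correlation was 0.456 (from -0.35 to 0.918), and the median Spearman correlation was 0.431. In a permutation test over the clock times and feeding groups, 1000 random exchanges of the replicate numbers gave at most 0.101 and 0.097 (permutation p = 0.001 for both, the smallest they can give). Without the 2 farthest points of each pair the median Pearson correlation was 0.31. By tissue the median ran from -0.068 in the pancreas and -0.036 in the duodenum to 0.675 in the kidney cortex. The same mice behind the same label in different tissues are a candidate explanation, and tissues would then not be independent replicates. Shared handling by label was not tested, since the labels give no batch.

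The scores were lowest in ALF and highest in TRF by construction, with 24 labels of each. Some ALF labels lay between: the mean over 16 tissues was 0.05 (SD 0.65) for ZT12 replicate 2 and -0.07 (SD 0.43) for ZT0 replicate 1. In eWAT at ZT10 the ALF library of replicate 2 scored 0.669 and the TRF library of replicate 1 scored -1.118, while the iWAT libraries with these labels scored -1.285 and 0.797. Without ZT10 the eWAT count was 9099. The duodenum library of TRF at ZT4, replicate 2, correlated better with the mean ileum profile (0.9855) than with its own (0.9658), and the ileum library with the same label better with the duodenum (0.9844) than with its own (0.9609). In all 13 libraries lay nearest another tissue. No library was given another label.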
